A study of Mus musculus with 6 samples.

How the data were processed

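RNA of mouse embryos at the 4-cell stage was measured in 6 libraries, 3 of untreated controls and 3 of embryos exposed to an LDHB inhibitor. Per the labels' protocols, full-length complementary DNA was made from a few cells with an oligo(dT) primer, amplified by PCR, fragmented and sequenced with paired ends. Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR with the mouse build GRCm38, and the roles of these tools and the annotation release are not given in the sources used here. The labels mention neither molecular identifiers nor strand, so overlapping and antisense genes cannot be told apart by the values. How reads shared by near-identical copies were assigned is not given in the sources used here, so the levels of such genes are uncertain.

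The authors deposited FPKM per gene and library, per the file headers. Low values did not fall on steps, so no reads were recovered, the depth is unknown, and no counting interval or floor is given. Of the 78 ribosomal protein genes 0 were at 0 in any library, and a gene at 0 is described only as listed at 0. The fold change in the authors' deposited table is the ratio of the group means of FPKM, with a mean of 0 replaced by 1e-04, and its log2 stands beside it. The p-value and q-value per gene are the authors' own. The q-value is the Benjamini-Hochberg adjustment over all genes listed, and the genes the authors marked have a q under 0.05 and an absolute log2 fold change of at least 1, as checked on the values. Which tool gave the p-value is not given in the sources used here. The enrichment tables the authors deposited give a p-value and q-value per term, and gene numbers treated as a score, per the file headers.

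Groups and replicate numbers came from the sample titles. Values were analysed as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with a trended and robust empirical Bayes fit, for genes with a mean of at least 1 FPKM over the 6 libraries, and Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes. The test planned for read counts was not used, since the table holds FPKM. The 32 gene lists were fixed before the data were examined, and the 28 with at least 3 tested genes were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, which tests whether the genes of a list move, on balance, one way, without comparing them with other genes. Library totals and shares were compared by exact two-sided permutation tests, whose smallest p is 0.1.

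Genes were named by a fixed rule. It took the lactate dehydrogenase and malate-aspartate shuttle genes, and in each direction the 10 with the largest fold change past the threshold. Where fewer than 5 passed, as here, it took the 10 with the smallest unadjusted p among genes with a symbol that is not a predicted model, a mean of at least 5 FPKM in the higher group and groups that did not overlap. In each list it took up to 4 genes past the threshold, or else the 2 with the smallest p. Named outside it, after their values were seen, were Zscan4c, Zscan4f, Obox6, Gm5662, Prdx2, mt-Nd1, mt-Nd3, mt-Co1, Gapdh, Tgfbi, Raver1, Gm4301 and 1500002C15Rik. Of the 29431 gene identifiers 29348 were found in GENCODE M21, which is on the same build and gave the coordinates.

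The fit was tested on simulated data with the means of the real genes and the spreads the fit estimated for them, the same in every library. In these data 100 genes were changed per fold size, the proteasome genes were shifted as well, and 126 of 9361 genes were called. Of the changed genes that stayed above the filter 37.4% were recovered at a log2 fold change of 1 and 93.4% at 2, with 6 calls on unchanged genes. The simulated genes varied independently, so the lists were not tested there under correlation between genes. Alternatives covered the pseudocount, the filter, the scaling, leaving out predicted models, each library left out, the replicate number as a block, library weights, the thresholds and the list tests. A fit without trend and robustness, and a hypergeometric test of KEGG pathways against the 6332 annotated genes of the table, were added after seeing the data. GO terms were not used here for such a test. Transcript length and GC content came from the longest transcript per gene of GENCODE M21, and near-identical copies (at least 95% identity over at least 100 bases for mitochondrial genes and over at least 50% of the transcript for 2-cell genes) from BLAST 2.17.0. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.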

Results

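RNA was measured in mouse embryos at the 4-cell stage, wild type by their labels, in 3 libraries of untreated controls and 3 libraries of embryos exposed to an inhibitor of lactate dehydrogenase B (LDHB), named AXKO-0046 in the labels. LDHB is the lactate dehydrogenase subunit associated with the oxidation of lactate to pyruvate. The series description speaks of 6 embryos, and its wording leaves open whether these are counted per group or per library. Nothing in the labels says that the replicates came from separate litters or cultures, so the p-values measure only the spread between these libraries, which may be technical. The authors' deposited table gives FPKM for 29431 genes, and the depth of each library is unknown. The control libraries listed 20997, 21803 and 22142 genes above 0, and the inhibitor libraries 21731, 21718 and 20094. Genes with a mean of at least 1 FPKM, 9691 in number, were tested.

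The first question was how the targeted enzyme was expressed. Ldhb (ENSMUSG00000030246, chromosome 6, 142490249 to 142507957, minus strand, GRCm38) was measured at 24.04, 22.7 and 52.01 FPKM in the control libraries and at 45.5, 16.02 and 20.6 FPKM in the inhibitor libraries. The difference was -0.29 on the log2(FPKM + 1) scale (SE 0.45, limma adjusted p = 0.869), and the groups overlapped. Ldha, the subunit that predominates in glycolytic tissues, averaged 2.89 FPKM ± 1.24 in controls and 2.82 FPKM ± 1.62 under the inhibitor, and Ldhc, the testis-enriched form, 6.05 FPKM ± 1.94 and 4.57 FPKM ± 2.17 (SD, n = 3 each). The compound acts on the protein, so the transcript level does not check the treatment. The sign of the Ldhb difference rested on single libraries: it was 0.083 without control replicate 3 and 0.0084 without inhibitor replicate 2.

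The series title names the malate-aspartate shuttle, which carries reducing equivalents from the cytosol into mitochondria. Of its 8 listed genes 7 were tested, with 4 fold changes above 0 and 3 below, and the list did not pass (median 0.0019, mean -0.064, camera adjusted p = 0.915). Mdh2, the mitochondrial malate dehydrogenase, averaged 219.6 FPKM ± 13.04 in controls and 245 FPKM ± 58.6 under the inhibitor, and Mdh1, its cytosolic counterpart, 4.72 FPKM ± 0.134 and 4.77 FPKM ± 0.868 (SD, n = 3 each). Got1, the cytosolic aspartate transaminase, averaged 10.2 FPKM ± 1.48 and 9.51 FPKM ± 3.75, and Slc25a11, the oxoglutarate carrier, 9.34 FPKM ± 4.26 and 6.49 FPKM ± 2.61. The aspartate-glutamate carriers Slc25a12 and Slc25a13 averaged 5.07 FPKM ± 0.179 and 5.50 FPKM ± 1.23, and 1.49 FPKM ± 0.704 and 0.798 FPKM ± 0.329, in that order. Got2, the mitochondrial transaminase, was the member whose 3 inhibitor libraries all lay above the controls, at 2.07 FPKM ± 0.322 against 1.39 FPKM ± 0.255 (limma adjusted p = 0.676). Slc25a22 averaged under 1 FPKM and was not tested.

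Protein-coding transcripts of mitochondrial DNA were lower under the inhibitor. All 13 had fold changes below 0, with a median of -0.71 on the log2 scale, while under quantile normalization 11 did, with a median of -0.52. In 10 of them all 3 inhibitor libraries lay below all 3 controls. Of all 9691 genes tested 607 lay in that order, and chance gives 10% of genes for both orders together. The 13 genes vary together (camera's estimated correlation 0.35), so the 10 are not separate observations. The list fell relative to other genes by camera with a preset correlation (adjusted p = 6.04e-14), and the call was lost with fry (adjusted p = 0.0912) and with camera (adjusted p = 0.581 with an estimated correlation). Adjusted over the list alone 9 of the 13 fell in limma, and over all genes tested 0 did, with 9 at an unadjusted p under 0.05. mt-Atp6, an ATP synthase subunit (ENSMUSG00000064357, mitochondrial chromosome, 7927 to 8607), averaged 22219 FPKM ± 2139 in controls and 11599 FPKM ± 1959.6 under the inhibitor (SD, n = 3 each), a log2 fold change of -0.95 (SE 0.17, limma adjusted p = 0.353). mt-Cytb, of complex III, averaged 17491 FPKM ± 2198 and 8693 FPKM ± 2332, and mt-Nd4l, of complex I, 793 FPKM ± 31.4 and 375 FPKM ± 97.7. The fold changes were uneven, from -1.21 for mt-Nd3 to -0.26 for mt-Nd1 and -0.051 for mt-Co1. Under quantile normalization mt-Nd1 was at 0.043, mt-Co1 at 0.13 and mt-Atp6 at -0.15. Nuclear genes near-identical to these transcripts, 11 in the table, may share their reads, so the level of each gene is uncertain.

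**Figure D1:**
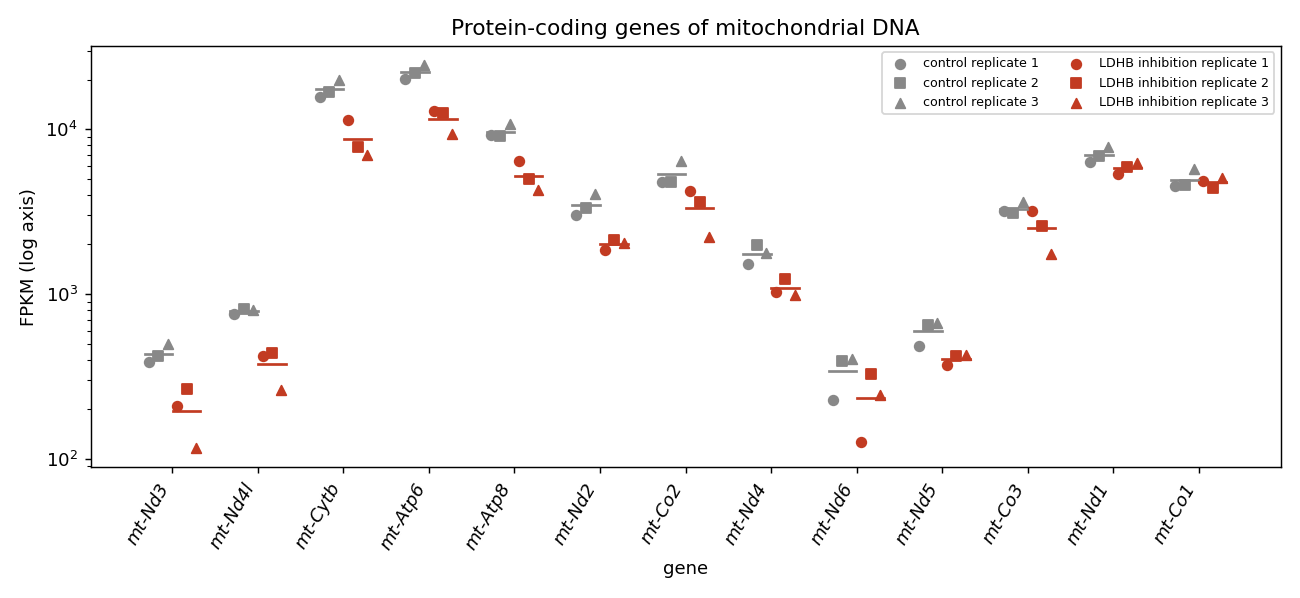
FPKM on a log axis of the 13 protein-coding genes of mitochondrial DNA, with 1 point per library and a line at each group's mean. Grey is control and red LDHB inhibition, with circles, squares and triangles for replicates 1, 2 and 3. Genes are ordered by log2 fold change in the limma fit (mt-Nd3 first, mt-Co1 last). All inhibitor libraries lie below all controls in 10 of the genes, while under quantile normalization mt-Nd1 and mt-Co1 had fold changes above 0.

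The same difference appeared in the share of FPKM taken by all genes of mitochondrial DNA. It was 15.1%, 16.7% and 18.9% in the control libraries and 11.98%, 11.2% and 10.6% in the inhibitor libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The 10 most abundant genes of each library took 21.98% ± 1.70 of FPKM in controls and 15.99% ± 0.950 under the inhibitor (SD, n = 3 each; exact permutation p = 0.1). The total FPKM was 518333 ± 6523 and 481974 ± 21956 (exact permutation p = 0.1). Coding genes of mitochondrial DNA alone took 14.9% ± 1.53 and 9.58% ± 0.965 of FPKM. They enter the top genes and the total too, so these differences are not separate observations. The number of genes above 0 averaged 21647 ± 588 and 21181 ± 941 (exact permutation p = 0.5), and that of genes at 1 FPKM or more 9343 ± 224 and 9666 ± 337 (exact permutation p = 0.3). Predicted gene models took 27.3% ± 0.272 and 28.01% ± 4.48 of FPKM (exact permutation p = 1).

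Nuclear-encoded subunits of oxidative phosphorylation were higher under the inhibitor. Of 71 tested, 62 had fold changes above 0, with a median of 0.28. Under median-ratio scaling 54 did, and under quantile normalization 52. The list rose by camera with a preset correlation (adjusted p = 1.62e-05). The call was lost with fry (adjusted p = 0.318) and with camera (adjusted p = 0.806 with an estimated correlation). In 17 genes all inhibitor libraries lay above all controls, against 1 in the opposite order. Of all 9691 genes tested 885 lay in the first order and 607 in the other. The genes of this list vary together (camera's estimated correlation 0.20), so the 17 are not separate observations. In limma 0 members passed over all genes tested or adjusted over the list alone. At an unadjusted p under 0.05, 9 were higher and 0 lower. Atp5a1, the alpha subunit of ATP synthase, averaged 33.8 FPKM ± 3.24 in controls and 56.1 FPKM ± 9.26 under the inhibitor (SD, n = 3 each; limma adjusted p = 0.422), and Ndufa4, a small respiratory chain subunit, 42.3 FPKM ± 3.91 and 65.6 FPKM ± 15.4 (limma adjusted p = 0.493).

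Subunits of the proteasome, which degrades ubiquitinated proteins, were also higher. Of 31 tested, 28 had fold changes above 0, with a median of 0.27, and in 12 all inhibitor libraries lay above all controls. Among all 9691 genes tested 885 lay in that order. These subunits vary together too (camera's estimated correlation 0.20), so the 12 are not separate observations. Under median-ratio scaling, and also under quantile normalization, 26 of the 31 had fold changes above 0. The list rose by camera with a preset correlation (adjusted p = 1.65e-05), and the call was lost with fry (adjusted p = 0.197) and with camera (adjusted p = 0.768 with an estimated correlation). Over all genes, or adjusted over the list alone, 0 members passed in limma, with 6 higher at an unadjusted p under 0.05. Psmb6, a catalytic core subunit, averaged 189 FPKM ± 21.4 in controls and 318 FPKM ± 43.2 under the inhibitor, and Psma5, another core subunit, 393 FPKM ± 39.05 and 572 FPKM ± 53.2 (SD, n = 3 each).

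Maternal oocyte transcripts and ribosomal protein transcripts lay lower. Of 22 maternal genes tested, 18 had fold changes below 0, with a median of -0.23, and camera called the list with a preset correlation (adjusted p = 0.00124; adjusted p = 0.806 with an estimated correlation). Oosp1, an oocyte-secreted protein, fell adjusted over the list alone (adjusted p = 0.0323), averaging 15.3 FPKM ± 2.16 in controls and 5.37 FPKM ± 2.72 under the inhibitor (SD, n = 3 each), and did not pass over all genes (limma adjusted p = 0.378). Npm2, a maternal histone chaperone, averaged 33.3 FPKM ± 2.43 and 20.7 FPKM ± 3.02. Of 78 ribosomal protein genes 56 had fold changes below 0, with a median of -0.084 (camera adjusted p = 0.00395; adjusted p = 0.961 with an estimated correlation), and in limma 0 passed over all genes or adjusted over the list alone, with 1 lower and 0 higher at an unadjusted p under 0.05. Rpl7 averaged 418 FPKM ± 36.7 and 322 FPKM ± 51.1, and Rpl21 5.48 FPKM ± 0.542 and 3.22 FPKM ± 0.799. The maternal list's median was -0.36 without control replicate 1, -0.38 without control replicate 2, -0.37 without inhibitor replicate 1 and -0.12 without inhibitor replicate 3, and the list passed in each. It was -0.0084 without control replicate 3 (camera adjusted p = 0.358) and -0.12 with library weights (adjusted p = 0.0649), and over all alternatives, the other list tests included, the adjusted p ran from 2.41e-05 to 0.806. The ribosomal list's median was -0.17 under median-ratio scaling, with 70 fold changes below 0, -0.13 without control replicate 2 and -0.13 without inhibitor replicate 1, and the list passed in each. It was 0.0043 without control replicate 1 (camera adjusted p = 0.920), -0.012 without inhibitor replicate 2 (adjusted p = 0.831) and -0.049 with library weights (adjusted p = 0.117), with a range over the same alternatives of 2.07e-05 to 0.961.

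**Figure D2:**
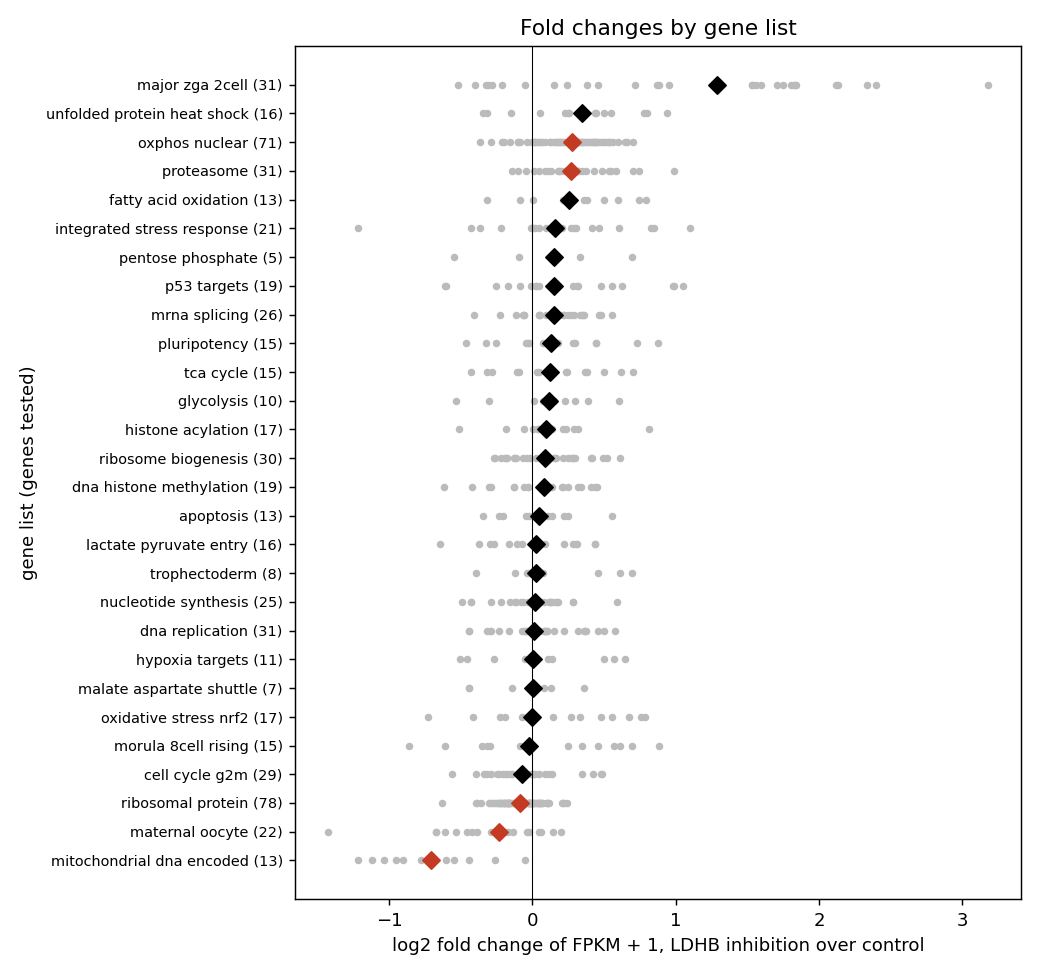
Log2 fold change of FPKM + 1 (LDHB inhibition over control) of each tested gene (grey points) in the 28 gene lists tested, with the list median as a diamond, red where camera with a preset correlation gave an adjusted p under 0.05. The mitochondrial-DNA list has a median of -0.71, and 0 lists passed by camera with an estimated correlation, with 1 at an unadjusted p under 0.05.

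Genes of the 2-cell stage, when the embryonic genome is first broadly transcribed, had a list median of 1.29 over 31 tested genes, and the list did not pass (camera adjusted p = 0.0810). The highest values were mostly in inhibitor replicate 2, and 9 of the genes had no near-identical copy, so the levels of the others, which may share reads, are uncertain. Zscan4c, a gene of a cluster active at the 2-cell stage, was at 136 FPKM there and between 0.187 and 1.34 FPKM in the other 5 libraries, and its paralog Zscan4f was at 363 FPKM there and at most 2.53 FPKM elsewhere. In 27 of the 31 genes that library was the highest of the 6. Without it the list median was -0.25 (camera adjusted p = 0.231). The list passed under median-ratio scaling (adjusted p = 0.0181) and quantile normalization (adjusted p = 0.0114), and without control replicate 2 (adjusted p = 0.0437), inhibitor replicate 1 (adjusted p = 0.000986) or inhibitor replicate 3 (adjusted p = 0.00373), and over all alternatives, the other list tests included, the adjusted p ran from 0.000986 to 0.961. Usp17lc, of a deubiquitinase family, was at 19.4 FPKM in inhibitor replicate 2, at 0.124 and 1.67 FPKM in the other inhibitor libraries and at most 0.225 FPKM in controls. Sp140 averaged 24.2 FPKM ± 6.70 in controls and 16.6 FPKM ± 5.24 under the inhibitor (SD, n = 3 each). Across all tested genes inhibitor replicate 2 had a median Pearson correlation with the other libraries of 0.888, against 0.946 to 0.965 for the rest, over genes that are not independent replicates. Its score on the first principal component (50.5% of the variance) was 76.2, where the others lay between -23.8 and -7.74. On the second component (18.8%) inhibitor replicate 3 stood at -47.01 and the others between 4.68 and 11.2.

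**Figure D3:**
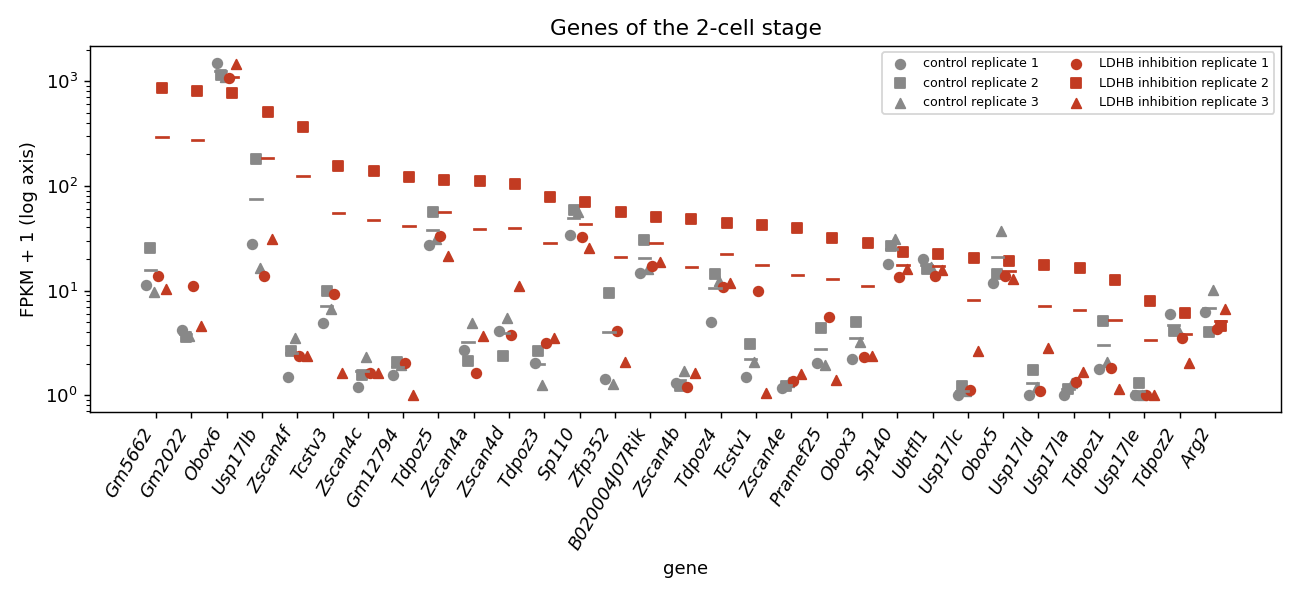
FPKM + 1 on a log axis of the 31 tested genes of the 2-cell stage, ordered by their value in inhibitor replicate 2, with 1 point per library (grey, control; red, LDHB inhibition; circles, squares and triangles for replicates 1, 2 and 3) and a line at each group's mean. The red squares of inhibitor replicate 2 are the highest points in 27 of the genes.

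Among single genes, Ifitm2, an interferon-induced transmembrane protein, had the smallest p of the named genes. It averaged 86.4 FPKM ± 20.3 in controls and 258 FPKM ± 14.6 under the inhibitor (SD, n = 3 each), a log2 fold change of 1.59 (SE 0.20, limma adjusted p = 0.175; ENSMUSG00000060591, chromosome 7, 140954837 to 140955987, minus strand). It passed in 1 alternative, with predicted models left out and a library total without mitochondrial genes. The log2 fold change there was 1.61 (limma adjusted p = 0.0475, with 0.0475 to 0.753 over the alternatives). The other genes with higher values named by the fixed rule were Rtn4r, Cyp2s1, Tmed2, Trmt2a, Tmem185a, Exosc4, Psmb6, Tmem267 and Acat2, and none of them passed (limma adjusted p = 0.378 for each). Tmed2, a cargo receptor of the early secretory pathway, averaged 115 FPKM ± 11.9 and 203 FPKM ± 36.6, and Exosc4, a subunit of the RNA exosome, 47.9 FPKM ± 1.32 and 79.3 FPKM ± 8.10. Those with lower values were the mitochondrial transfer RNAs mt-Tr, mt-Tt and mt-Tm, the coding genes mt-Atp6, mt-Nd4l, mt-Atp8, mt-Cytb and mt-Nd2, and the nuclear genes Obox8 and Prr23a1. None of these passed either (limma adjusted p = 0.353, and 0.378 for mt-Nd2). Each transfer RNA lies beside a coding gene named here, mt-Tr by mt-Nd4l, mt-Tt by mt-Cytb and mt-Tm by mt-Nd2. Whether the values of the transfer RNAs are reads of these neighbours was not tested. Obox8, a homeobox gene, averaged 763 FPKM ± 121 and 388 FPKM ± 50.8, and Prr23a1 109 FPKM ± 25.1 and 40.3 FPKM ± 12.2.

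Over all 9691 genes limma called 0 higher and 0 lower at an FDR of 0.05. At an unadjusted p under 0.05 there were 457 higher and 368 lower genes, 825 in all, where chance would give 485. The inhibitor libraries all lay above all controls in 885 genes and below them in 607, together 15.4% of genes, where chance gives 10%. The split depended on the scaling: it was 295 higher and 511 lower genes under median-ratio scaling, and 268 and 543 under quantile normalization. The 457 higher genes became 291 without control replicate 2, 304 without control replicate 3 and 751 without inhibitor replicate 3, and the 368 lower ones 231 without control replicate 2. At an FDR of 0.05, leaving out inhibitor replicate 1 gave 12 calls in limma, 11 higher and 1 lower. All were predicted models, such as Gm4301 (log2 fold change 7.18). Gm4301 was at 324 and 108 FPKM in inhibitor replicates 2 and 3, 0.120 FPKM in replicate 1 and at most 0.411 FPKM in controls. Whether these models share reads was not tested. Leaving out inhibitor replicate 2 gave 1 call, 1500002C15Rik (log2 fold change 3.53).

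Stress and metabolic lists did not pass. In the unfolded protein and heat shock list 13 of 16 genes had fold changes above 0 (camera adjusted p = 0.0709), with Hspa5, the chaperone BiP, at 32.4 FPKM ± 3.41 in controls and 67.6 FPKM ± 33.01 under the inhibitor (SD, n = 3 each). This list passed without control replicate 2 (adjusted p = 0.00321), with no filter on low values (adjusted p = 0.0186) and under quantile normalization (adjusted p = 0.0497), with a range of 0.00321 to 0.806 over all alternatives, the other list tests included. In the fatty acid oxidation list 11 of 13 fold changes were above 0 (camera adjusted p = 0.0709), with Acadl, a mitochondrial acyl-CoA dehydrogenase, at 16.2 FPKM ± 2.09 and 29.3 FPKM ± 7.64. Of 21 integrated stress response genes tested 15 were above 0 and 6 below (camera adjusted p = 0.714). Nars, an aminoacyl-tRNA synthetase of that list, averaged 42.8 FPKM ± 1.35 and 65.9 FPKM ± 8.18, and Nupr1, a stress-induced transcription regulator, 22.996 FPKM ± 2.82 and 10.1 FPKM ± 5.67. Among p53 targets, with 13 of 19 fold changes above 0 (camera adjusted p = 0.503, and 0.0242 without control replicate 2, with 0.0242 to 0.961 over the same alternatives), Cdkn1a, which encodes the cell cycle inhibitor p21, averaged 15.7 FPKM ± 4.84 and 32.8 FPKM ± 11.9. In the oxidative stress list, with 9 of 17 fold changes above 0 and 8 below (camera adjusted p = 0.773), 2 genes were higher and 1 lower at an unadjusted p under 0.05. Of these Sod1, a superoxide dismutase, averaged 8.42 FPKM ± 0.958 and 15.2 FPKM ± 1.20, and Prdx2, a peroxiredoxin, 28.005 FPKM ± 7.34 and 16.9 FPKM ± 6.02. In the list of lactate and pyruvate entry, with 9 of 16 fold changes above 0 (camera adjusted p = 0.915), Me1, the cytosolic malic enzyme, averaged 3.99 FPKM ± 0.709 and 2.21 FPKM ± 0.546. Over all genes none of the genes named here from these lists passed (limma adjusted p from 0.409 to 0.575). The camera adjusted p was 0.915 for glycolysis and for histone acylation, 0.887 for the tricarboxylic acid cycle, 0.964 for apoptosis and 0.356 for the G2 and M phases. For splicing it was 0.181, and 0.0336 with no filter on low values, with 0.0336 to 0.768 over the same alternatives. Of 23 glycolysis genes 10 were tested, and Gapdh, which has many pseudogenes, was listed at 0.0388 to 0.163 FPKM. That low level, and with it the gene's place below the filter, is uncertain, since how reads shared with the pseudogenes were assigned is not given in the sources used here.

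The remaining lists fixed beforehand did not pass either. The camera adjusted p was 0.915 for pluripotency, trophectoderm and rising 8-cell genes, 0.945 for DNA replication and the pentose phosphate pathway, 0.849 for nucleotide synthesis, 0.801 for ribosome biogenesis, and 0.964 for hypoxia targets and for DNA and histone methylation. Median and mean fold changes differed in sign for nucleotide synthesis (0.016 and -0.0028) and rising 8-cell genes (-0.022 and 0.084), and both medians changed sign under quantile normalization (-0.078 and 0.12). Lactate and pyruvate entry, DNA replication, apoptosis, and DNA and histone methylation had medians above 0 without further scaling and below 0 under quantile normalization. Their means were above 0 and their camera direction was down, as camera compares a list with the other genes, and the median of all tested genes was 0.062. Hdac2, a histone deacetylase, averaged 23.04 FPKM ± 5.80 in controls and 40.5 FPKM ± 3.55 under the inhibitor (SD, n = 3 each; limma adjusted p = 0.423), in the histone acylation list with 14 of 17 fold changes above 0. Kdm4c, a histone demethylase, averaged 12.5 FPKM ± 0.387 and 7.80 FPKM ± 0.355 (limma adjusted p = 0.462), in the list of DNA and histone methylation with 10 of 19 fold changes above 0. Of the glycerol phosphate shuttle 2 genes were tested, too few for a list test: Gpd2, its mitochondrial enzyme, averaged 9.86 FPKM ± 1.96 and 14.9 FPKM ± 1.06 (limma adjusted p = 0.534). The 13 cumulus and granulosa markers in the table summed to at most 1.31 FPKM in any library, and the 4 sperm markers to at most 1.48 FPKM. Of the 6 blood markers with values, only 2 reached a mean of 1 FPKM over the libraries, the alpha globins Hba-a1 and Hba-a2. Hba-a1 averaged 128 FPKM ± 24.6 in controls and 102 FPKM ± 33.03 under the inhibitor, and Hba-a2 32.6 FPKM ± 6.14 and 29.3 FPKM ± 11.1. The other blood markers lay below that mean, and whether blood was present was not tested.

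The authors' deposited table marks 233 genes as significant, 129 higher and 104 lower under the inhibitor. Of the calls in the authors' deposited table, 110 were listed at 0 in all libraries of one group, and 46 (19.7%) were above 0 in 1 library only, 34 of them higher, against 16.8% of all genes listed. The groups did not overlap in 158 of the calls in the authors' deposited table, 66 higher and 92 lower. These genes were selected for a difference between the same libraries, so the 10% that chance gives for unselected genes does not apply to them. Raver1, with the smallest p in the authors' deposited table, was listed at 0 in all inhibitor libraries and at 1.66, 3.003 and 1.71 FPKM in controls. Tgfbi, next by p in the authors' deposited table, was at 1.20 FPKM in inhibitor replicate 3 and listed at 0 in the other 5 libraries. Among the genes marked in the authors' deposited table, 100 had a mean of at least 1 FPKM. All 100 had the same direction in the limma fit, where 71 had an unadjusted p under 0.05 and 0 passed an FDR of 0.05. Across tested genes, which are not independent replicates, the fold changes of the authors' deposited table and of the fit on the same libraries had a Spearman correlation of 0.977.

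In the authors' deposited table of GO terms 0 of 1319 had a q under 0.05, and 354 an unadjusted p under 0.05. The smallest q there, 0.0608, was that of the NADH dehydrogenase complex, with 2 lower genes, mt-Nd4l and mt-Nd3. The term holds only these 2 genes in the authors' background. Both are coding genes of mitochondrial DNA, which vary together, so they are not separate observations. Nucleic acid binding followed in the authors' deposited table, with 13 higher and 9 lower genes (q = 0.102). In the authors' deposited table of KEGG pathways 0 of 134 had a q under 0.05, and 13 an unadjusted p under 0.05. Axon guidance came first in the authors' deposited table (5 marked genes, q = 0.287), and oxidative phosphorylation had 3 lower genes (q = 0.509). Of all terms, 1015 GO terms and 92 pathways held a single gene among those the authors marked, whatever the size of the term.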

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

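The alternatives were fixed before the data were examined, except the fit without trend and robustness and the recomputed KEGG test, which were chosen after seeing the data. Those planned for read counts were not run, since the table holds FPKM, and with the depth unknown its limits cannot be computed. Genes past an FDR of 0.05 numbered 0 in limma as reported, 1 with predicted models left out and a total without mitochondrial genes, and 0 to 12 with a library left out (12 without inhibitor replicate 1, 1 without inhibitor replicate 2). The other alternatives gave 0, including an FDR of 0.1 and the added fit, where 465 genes were higher and 356 lower at an unadjusted p under 0.05. At that p the 457 higher genes became 259 with a mean of at least 5 FPKM (fewer genes tested), 295 under median-ratio scaling, 268 under quantile normalization, and 291 to 751 with a library left out (291 without control replicate 2, 304 without control replicate 3, 751 without inhibitor replicate 3). The 368 lower genes became 622 with no filter (more genes tested), 206 with a mean of at least 5 FPKM, and 231 to 438 with a library left out (231 without control replicate 2). Other causes were not tested. The median fold change of all tested genes moved by -0.066 under median-ratio scaling and -0.088 under quantile normalization.

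Of the lists 5 passed as reported, 0 with an estimated correlation (1 at an unadjusted p under 0.05), 0 with fry (4 at an unadjusted p under 0.05), 3 with library weights, and 4 to 8 with a library left out (8 without control replicate 2). In the alternatives that kept camera's preset correlation, the mitochondrial-DNA median lay between -0.87 and -0.52 (adjusted p at most 1.11e-06), that of nuclear oxidative phosphorylation between 0.19 and 0.35 (at most 0.0254) and that of the proteasome between 0.19 and 0.35 (at most 0.0254). The mitochondrial share difference of -5.61 percentage points was -7.53 with predicted models left out. The authors' 233 calls became 280 with no fold threshold, and the recomputed KEGG test passed 0 pathways (smallest q 0.372).

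Same-numbered libraries had correlations of deviations of 0.136, 0.202 and 0.0368, and the other pairs across the groups -0.194 to 0.0546. The value of 0.0368 lies within the range of the other pairs. The numbers were therefore not taken to pair the libraries, though a pairing is not excluded. With the replicate block 0 genes passed, 485 were higher and 392 lower at an unadjusted p under 0.05, and 6 lists passed, the 2-cell list among them (adjusted p = 0.00736).

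Among 84 named genes and 28 lists, 66 of 1824 comparisons changed sign while passing no threshold in either setting, and the cause was not tested. Ldhb became 0.029 with library weights and ranged from -0.72 to 0.083 with a library left out. Ldha became 0.059 with weights (range -0.37 to 0.29), Mdh1 -0.066 under median-ratio scaling, -0.099 under quantile normalization and -0.018 with weights (range -0.12 to 0.064), and Slc25a12 -0.030 under quantile normalization (range -0.049 to 0.23). With a library left out Mdh2 ranged from -0.041 to 0.30, Got1 from -0.41 to 0.11, Gpd1l from -0.28 to 0.0070 and Hba-a2 from -0.47 to 0.080.

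List medians that changed sign under both median-ratio scaling and quantile normalization were lactate and pyruvate entry (-0.049 and -0.082), the malate-aspartate shuttle (-0.066 and -0.099), nucleotide synthesis (-0.065 and -0.078), trophectoderm (-0.037 and -0.062), DNA replication (-0.055 and -0.076), apoptosis (-0.036 and -0.046), oxidative stress (-0.043 and -0.030) and hypoxia targets (-0.068 and -0.071). Under quantile normalization alone rising 8-cell genes were at 0.12 and DNA and histone methylation at -0.049. With a mean of at least 5 FPKM the shuttle was at -0.030, trophectoderm at -0.077 and oxidative stress at -0.0074. Library weights gave -0.0063 for the shuttle and 0.019 for rising 8-cell genes. Trophectoderm was at -0.0028 with a pseudocount of 5 and -0.0021 with no filter, and oxidative stress at -0.0079 with a pseudocount of 0.1. With a library left out, list medians ranged from -0.035 to 0.11 for hypoxia targets, -0.067 to 0.34 for the integrated stress response, -0.017 to 0.13 for lactate and pyruvate entry, -0.25 to 2.03 for 2-cell genes, -0.049 to 0.063 for the shuttle, -0.38 to -0.0084 for maternal genes, -0.016 to 0.21 for rising 8-cell genes and -0.017 to 0.12 for nucleotide synthesis. They ranged from -0.035 to 0.24 for oxidative stress, -0.066 to 0.39 for the pentose phosphate pathway, -0.068 to 0.24 for pluripotency, -0.13 to 0.0043 for ribosomal proteins, -0.0087 to 0.18 for ribosome biogenesis and -0.019 to 0.28 for trophectoderm.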

Other observations

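The tests of library scaling and of nuclear copies for the mitochondrial genes, of maternal genes for inhibitor replicate 2, and of the mitochondrial-DNA list over the splits of the libraries, were chosen after the results were seen. Nuclear genes with near-identical sequence to the mitochondrial coding genes, 11 in the table, summed to 35539 FPKM ± 3778 in controls and 21138 FPKM ± 3398 under the inhibitor (SD, n = 3 each). The 13 coding genes summed to 77369 FPKM ± 8591 and 46285 FPKM ± 6135. The 2-cell list summed to between 1276 and 1689.8 FPKM in 5 libraries, where Obox6, a homeobox gene, made up most of the sum (1071 to 1501 FPKM), and to 4654 FPKM in inhibitor replicate 2. In that library Obox6 was lower than in the others, at 774 FPKM, and the highest gene of the list was Gm5662, at 849 FPKM against at most 24.6 FPKM elsewhere.

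The first pattern is the lower level of mitochondrial-DNA genes. Against library scaling as the whole cause, the median nearest to 0 under 3 scalings was -0.52, although under quantile normalization mt-Nd1 and mt-Co1 lay above 0. Against transcript length and GC content, removing their trend over nuclear genes left a median of -0.64. Against reads moving to nuclear copies, which would raise the copies, the summed FPKM of the copies changed by -46.3% of the size of the fall of the 13 genes, a decrease. An effect of the inhibitor on these transcripts stays open as a hypothesis, untested, beside differences in the state, number or handling of the embryos that these libraries do not separate.

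The second pattern is the high level of 2-cell genes in inhibitor replicate 2. Embryos of an earlier stage could account for it if maternal genes were also higher there, and their median difference from the other inhibitor libraries was -0.078 (quartiles -0.43 and 0.27), which decides nothing. Reads shared among near-identical copies might raise the list, and its 9 genes without such a copy had a median difference of 2.92 from the other 5 libraries (quartiles 0.46 and 3.69). The lower quartile fell short of the 0.5 set before that test, so shared reads stay open too. The pattern is in 1 library, and no other biological explanation was tested.

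The third pattern is the higher level of nuclear oxidative phosphorylation and proteasome genes. Once the trends of fold change on length, GC content and expression level were removed, the list medians stood 0.20 and 0.30 above that of all tested genes, against 0.22 and 0.21 before, which argues against these trends as the whole cause. Neither list passed with an estimated correlation, and the treatment and the state of the embryos stay open, untested.

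The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Each split other than the real one still sets unequal numbers of control and inhibitor libraries against each other. Such a split keeps part of any difference between the groups, so its counts do not show what chance alone gives. For genes past an FDR of 0.05 the real split gave 0, so 10 of 10 splits gave as many, and the highest of the others gave 1. At an unadjusted p under 0.05 the real split gave 825 genes, 1 split of 10 gave as many, and the highest of the others gave 578. For lists passing camera with the preset correlation the real split gave 5, 5 splits of 10 gave as many, and the others gave 3 to 7. For the mitochondrial-DNA list the absolute median was 0.71 in the real split and at most 0.45 in the others. Camera with the preset correlation called that list in the real split (adjusted p = 6.04e-14) and also in 5 of the 9 others (lowest adjusted p = 2.18e-05).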
